A study of Mus musculus with 8 samples.

How the data were processed

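The data were 8 mouse ChIP-seq libraries from a MiSeq instrument, 2 each for a control, PHF20, Wdr5 and Pol II. The groups and replicate numbers were taken from the sample titles. Whether the control was input DNA or a non-specific antibody is not given in the sources used here. The deposited files list the interval of each aligned read as 3 columns (chromosome, start and end), without strand, name or score, and there is 1 file per library. CASAVA 1.6, FastQC and Bowtie 0.12.7 are named with the mm9 build, per the submitters' processing notes, and their roles and mapping settings are not given in the sources used here. Every read interval in the files was 44 bp long. Reads that match several places of the genome can gather at high-copy stretches under some mapping settings, which bears on the pile-ups common to all libraries.

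All counts were made here from the deposited intervals. Reads that shared a chromosome and start were counted once, since the files carry no strand, and each was assigned to the window that held its midpoint, 22 bp from its start. Shifting reads by strand toward the fragment centre, which had been intended, was not possible. Library size was the number of these collapsed reads on the 19 autosomes and X. Coordinates are given from 1 on mm9.

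The planned comparisons were made in non-overlapping windows of 5 kb with a mean of at least 3 reads over the 8 libraries. Log2 CPM (counts scaled by library size in the usual way) with a prior count of 2 were fitted with limma-trend (limma 3.58.1 in R 4.3.3), all 8 libraries in one model with 1 mean per group and 4 residual degrees of freedom. Each ChIP group was compared with control, and windows with a Benjamini-Hochberg adjusted p under 0.05 were called. The rule for named windows was fixed before the data were examined: the 10 called windows with the largest change in each direction whose lowest ChIP library lay above, or highest below, both controls. All called windows passed it. A comparison of single values between 2 and 2 libraries cannot reach a two-sided exact permutation p below 0.333, so none is given.

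Comparisons at promoters, tests of gene lists, and shares of reads at promoters had been planned and were not run. The gene table at hand belongs to GRCm38, another build than that of the files, and its coordinates were not used. Gene names are therefore not attached to windows.

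Several analyses were added after the data had been seen. They were the 5 kb comparison of PHF20 with Wdr5, an exact binomial test of each ChIP replicate against both controls, and limma-trend on 1 kb windows. A count of 1 kb windows high in any pair of libraries against the other 6, at 6 settings of fold and read minimum, was added as well, with 0.3 CPM added to each value. For the held-out comparison, windows picked in 1 library were read in the other of its group against its mean over the surrounding 51 kb, with counts capped at 20 reads per window, and exact Poisson intervals at 95% were given. The local scan used the same background with a floor of 0.3 reads. For Wdr5, 4 kinds of analysis were thus tried at 1 kb after the 5 kb result was known: limma-trend with 2 references, the pair count, the held-out ratio and the local scan. The setting of the pair count that is described in full was chosen after all 6 had been seen and is among those most favourable to Wdr5. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these.

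The limma fits of PHF20 at 5 kb and of Wdr5 at 1 kb, the pair count and the local scan were tested on simulated libraries with windows raised by known folds. The held-out ratio, the exact binomial test and the other 5 kb comparisons were not. For PHF20 against control at 5 kb with control replicate 1 drawn like the other libraries, 0%, 40%, 96% and 100% of windows raised 2-fold, 4-fold, 8-fold and 16-fold were recovered, with 2 unchanged windows called among 435154. With the own profile of control replicate 1 over 100 kb bins, 2%, 26%, 82% and 100% were recovered and 17 unchanged windows were called, more than the threshold of 0.05 allows for. For Wdr5 at 1 kb, 2%, 38%, 100% and 100% were recovered against control, with 2 unchanged windows called, and 2%, 68%, 100% and 100% against the other 6 libraries, with 8. That simulation drew control replicate 1 like the other libraries and left 87999 windows past the filter, against 29867 in the data, so it describes the fit only roughly. The pair count recovered 79 of 100 windows raised 12-fold in the Wdr5 libraries and gave at most 1 in any other pair. This simulation drew all 8 libraries from 1 common density and used only the setting of 3-fold and 8 reads. Its counts for other pairs therefore need not hold in the data.

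The other settings for the 5 kb comparisons, fixed beforehand, were counting all reads, no low-count filter, a mean of at least 6 reads, size factors from 10 kb windows, a prior count of 0.5, voom weights, 20 kb windows, the replicate number as a block, and leaving out each library in turn. When a library is left out, the lone library of its group is assumed to vary as the other groups do.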

Results

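Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse cells of C57BL/6 background with antibodies against PHF20, Wdr5 and RNA polymerase II (Pol II), beside a control. PHF20 is a histone-reading subunit of an acetyltransferase complex, Wdr5 a core subunit of the complexes that methylate lysine 4 of histone H3, and Pol II the enzyme that transcribes protein-coding genes. The study set out to map where PHF20 and Wdr5 bind in embryonic stem cells. The labels of the single samples name neural progenitor cells derived from embryonic stem cells as the cell type, so the state of the cells was not settled from the labels. Each of the 4 groups held 2 libraries. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

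The libraries held between 2909981 and 5474884 aligned reads of 44 bp. Control replicate 1 was the deepest and control replicate 2 the shallowest. The PHF20 libraries held 4087956 and 4555093 reads, the Wdr5 libraries 4637163 and 3327665, and the Pol II libraries 3700072 and 3554691. Distinct read starts made up 84.3% of the reads in control replicate 1 and 65.6% in Pol II replicate 2, the highest and lowest shares among the 8 libraries. The median 5 kb window held 4 to 9 reads per library, so only large local differences were detectable at this depth.

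The 8 libraries shared one strong feature, a set of 42 windows of 5 kb in which every library held at least 20 times its own median. These windows took 10.6% to 17.3% of the reads of each library. The highest was on chromosome 2 from 98505001 to 98510000 (mm9), with 106599 to 281208 reads. A block on chromosome 9 from 3000001 to 3040000 and a window at 35110001 to 35115000 on the same chromosome were also among them. By this definition the control libraries shared these pile-ups, which took 12.3% and 10.6% of their reads.

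Control replicate 1 stood apart from the other libraries. Over 127916 windows of 20 kb, its read counts had a Spearman correlation of 0.04 to 0.16 with the other 7 libraries, whereas those 7 correlated at 0.74 to 0.85 with each other. Windows are not independent replicates, so these values describe the libraries and carry no test. Control replicate 1 had 4.20% of its distinct starts on the X chromosome and 0.11% on the mitochondrial genome, against 2.59% to 3.42% and 0.009% to 0.051% in the others. The log2 difference between replicates had an SD of 0.83 in the control group, 0.53 for PHF20, 0.65 for Wdr5 and 0.53 for Pol II. Every comparison with control therefore used a reference pair that differed more within itself than any ChIP pair did.

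The first comparison asked where PHF20 ChIP reads exceeded control. One stretch of chromosome 17 was higher in PHF20 ChIP, and no window was lower. The window from 35640001 to 35645000 (mm9) held 92.2 ± 13.4 CPM in PHF20 ChIP and 3.09 ± 2.52 in control (mean ± SD, n = 2 each). The distinct starts behind these values were 296 and 299 in PHF20 ChIP, and 6 and 11 in control. The Wdr5 libraries held 8 and 11 and the Pol II libraries 10 and 12 in the same window. The log2 fold change against control was 4.82 with a standard error of 0.50 (limma-trend, Benjamini-Hochberg adjusted p = 3.754e-16). The gene content of the window was not analysed here, because no annotation of the mm9 build was used.

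Within that window the PHF20 reads were concentrated between 35641001 and 35642900. This stretch held 287 and 290 distinct starts in the PHF20 libraries, 71.9 and 59.9 times the density of their own flanks. The other 6 libraries held 2 to 6 distinct starts there, between 0.42 and 1.62 times their flanks. Read starts fell off steeply on the right side. The last of the shared piled starts described next was at 35642888, and its reads ended at 35642931. In the 400 bp before that start the PHF20 libraries held 64 and 68 distinct starts, and in the 400 bp after that end 1 each. In the 50 bp from 35642901, PHF20 replicate 2 held 2 further starts, whose reads of 44 bp ran past that end. At 4 single positions, starting at 35641635, 35641997, 35642096 and 35642888, both PHF20 libraries held at least 10 reads and none of the other 6 libraries held any. These 4 positions carried 97 and 117 reads, or 19.4% and 24.5% of the reads in the stretch. The first and the end of the last lay 1297 bp apart. Outside the 42 shared windows, no other start on the autosomes or X had at least 10 reads in both PHF20 libraries and at most 1 in each of the others.

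**Figure D1:**
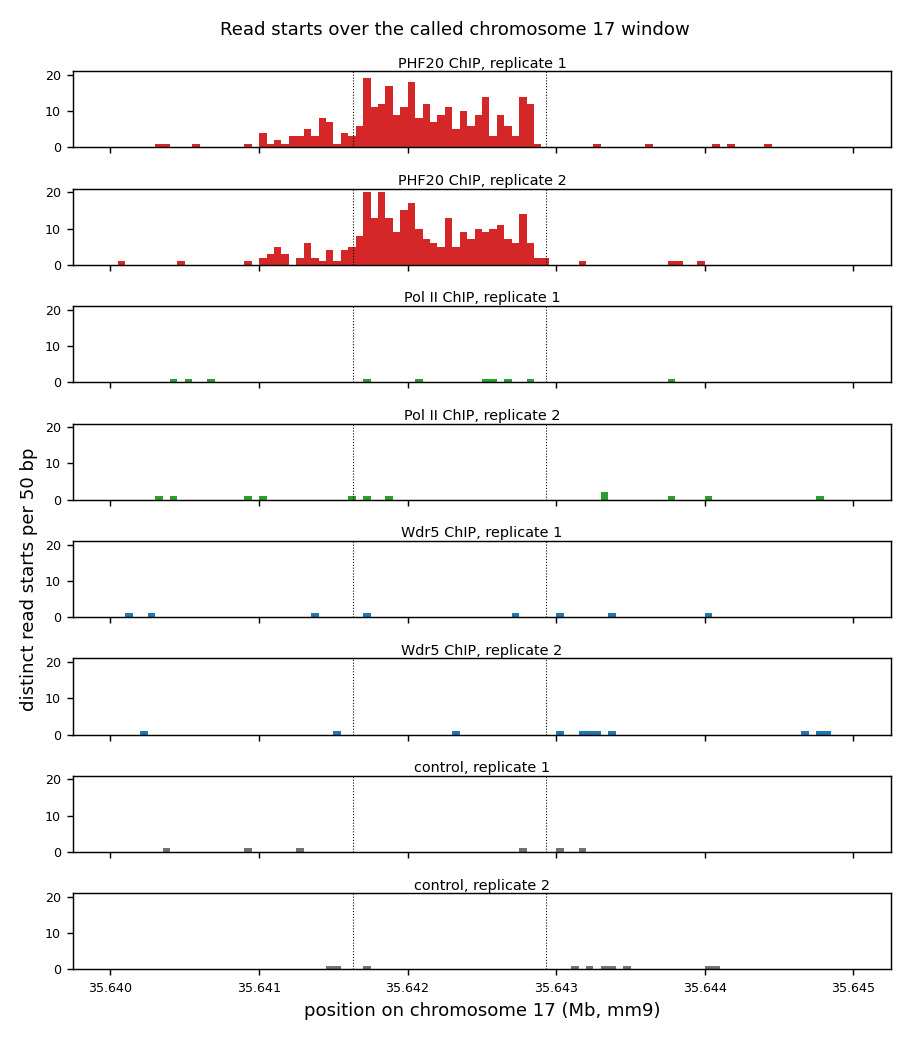
Distinct read starts per 50 bp (y axis) along the called 5 kb window of chromosome 17 (x axis, Mb, mm9), with 1 panel per library; the dotted lines mark 35641635 and 35642931. The 2 PHF20 libraries are filled between about these lines, with a lower level to the left, and the other 6 libraries hold only scattered starts.

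Beyond this stretch, no PHF20 window passed the threshold among the 456571 tested. Of the 456571, 13960 had an unadjusted p under 0.05 in limma-trend, a smaller share than the 0.05 that chance alone would give. In simulated libraries with the profile of control replicate 1, the same test for PHF20 against control recovered 26% of windows raised 4-fold and 82% of those raised 8-fold, and called 17 unchanged windows among 453319. The count rose to 2 without control replicate 1 and to 13, of which 1 was lower, without control replicate 2. An exact binomial test of both replicates called 3 windows, 1 higher and 2 lower.

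PHF20 ChIP was also set directly against Wdr5 ChIP, a comparison added over genome windows after the data were seen. The same chromosome 17 window was higher in PHF20 ChIP, with a log2 fold change of 4.64 and a standard error of 0.50 (limma-trend, adjusted p = 1.068e-14), and no other window differed. In this comparison 11980 of the 456571 windows had an unadjusted p under 0.05, again a smaller share than chance alone would give. With 20 kb windows the call was lost, and without Wdr5 replicate 1 there were 3 calls.

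The second comparison asked where Wdr5 ChIP reads exceeded control. At 5 kb no window passed the threshold by limma-trend. Of the 456571 tested, 21586 had an unadjusted p under 0.05, a share slightly below the 0.05 that chance alone would give. The voom variant of limma called 30 windows higher and 2 lower, and an exact binomial test called 1 higher and 3 lower. In all 30 of the higher voom windows control replicate 1 held at most 2 reads, and in 10 of them control replicate 2 held as many reads as the lower Wdr5 library or more. Without control replicate 2, limma-trend called 176 windows, 166 of them higher, and without Wdr5 replicate 1 it called 6, all lower.

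At 1 kb, a width added after the 5 kb windows had been examined, some windows were high in both Wdr5 libraries. Windows were counted in which both libraries of a pair held at least 8 reads and at least 3 times the level of each of the other 6 libraries. The Wdr5 pair gave 13 such windows on 11 chromosomes, and the 27 other pairs of libraries gave at most 2. The 2 PHF20 windows were the chromosome 17 stretch, and the Pol II pair and the control pair gave 0. Over the 13 windows the Wdr5 libraries held 180 and 150 reads in all, and each of the other 6 held between 8 and 22. The ratio of the Wdr5 mean to the mean of the other 6 libraries ran from 5.87 to 46.5 with a median of 10.8. These read counts and ratios, and the values of single windows below, follow in part from picking the windows on the same libraries. These 13 windows were singled out, and the setting of 3-fold and 8 reads chosen, after the counts of all 6 settings had been seen. The count depended on the thresholds: of 6 settings, the Wdr5 pair was the highest in 4, equalled the PHF20 pair at 2 windows in 1, and in 1 was passed by Wdr5 replicate 2 with Pol II replicate 2, at 15 against 17. With every deposited read counted, duplicates included, the same 2 libraries gave 15 windows and the Wdr5 pair 8.

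The highest of the 13 windows was on chromosome 2 from 158187001 to 158188000, with 15 and 17 reads in the Wdr5 libraries, 2 in PHF20 replicate 1 and 0 in the other 5 libraries. The next was on chromosome 15 from 76734001 to 76735000, with 5.15 ± 0.38 CPM in Wdr5 ChIP (mean ± SD, n = 2) and 0.45 ± 0.45 in the other libraries (n = 6). A window on chromosome 7 from 52973001 to 52974000 had 15 and 16 reads in the Wdr5 libraries and 0 to 3 in the others. The remaining windows lay on chromosomes 2, 4, 5, 6, 8, 12, 14, 16 and X, with 8 to 17 reads per Wdr5 library. In limma-trend on 29867 windows of 1 kb, Wdr5 ChIP exceeded control in 3 windows, with adjusted p between 0.019 and 0.022, and exceeded the other 6 libraries in 5, which included those 3. They were on chromosomes 4, 7, 8, 15 and 17, with log2 fold changes of 2.27 to 2.50 over the other 6 libraries, and 2 of the 5 were among the 13 windows. These limma calls were fragile. A prior count of 0.5 ended all of them. Leaving out 1 library leaves a single library in its group, so only the direction of change is given. Against control, the calls above were lost without control replicate 1 or Wdr5 replicate 2. Part of them were lost without PHF20 replicate 2, Wdr5 replicate 1 or control replicate 2. Against the other 6 libraries, the calls were lost without either PHF20 library, either Wdr5 library or Pol II replicate 2, and part of them without Pol II replicate 1. Without Wdr5 replicate 1, most calls in both comparisons were windows lower in Wdr5 ChIP. Lower windows were also called in both comparisons without control replicate 2, and against the other 6 libraries without control replicate 1.

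**Figure D2:**
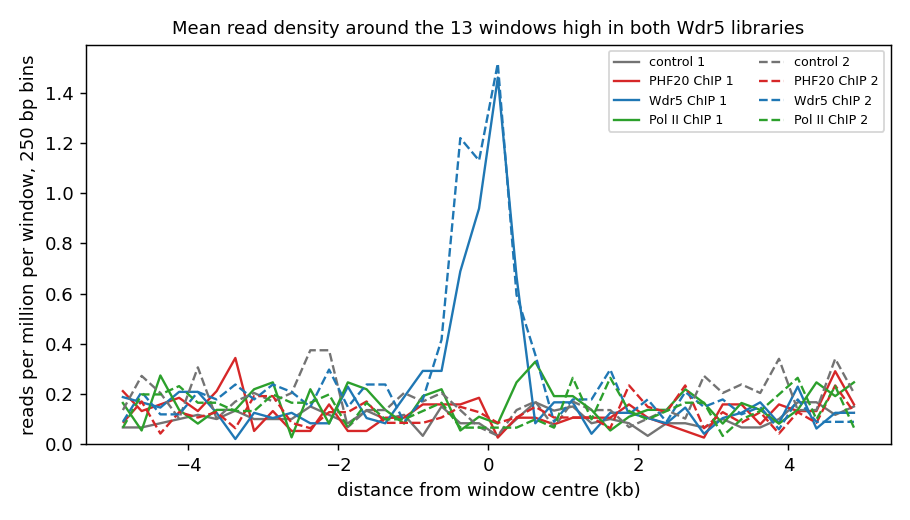
Mean CPM per window in 250 bp bins (y axis) by distance from the centre (x axis, kb) of the 13 windows of 1 kb high in both Wdr5 libraries; solid and dashed lines are replicates 1 and 2. The Wdr5 libraries rise within about 1 kb of the centre; the windows were selected to be high in Wdr5 and low in the other 6 libraries, so both features at the centre follow from the selection.

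Windows picked in one Wdr5 library were also above their surroundings in the other, which had taken no part in the choice. Windows of 1 kb were picked in 1 library against all libraries of the other groups, and were then read in the other library of the same group, relative to that library's own density in the surrounding 51 kb. The 83 windows picked in Wdr5 replicate 1 held 267 reads in Wdr5 replicate 2, 2.53 times the surroundings (95% exact Poisson interval 2.24 to 2.85). The 410 windows picked in Wdr5 replicate 2 held 1.47 times the surroundings in Wdr5 replicate 1 (1.39 to 1.56). For PHF20, without the chromosome 17 stretch, the ratios were 1.06 (0.93 to 1.205) and 1.00 (0.82 to 1.21). For Pol II they were 1.13 (0.98 to 1.31) and 1.08 (0.96 to 1.21), and for control 0.28 (0.25 to 0.32) and 0.92 (0.78 to 1.08). The intervals cover counting error only. With a minimum of 10 reads the first Pol II ratio was 1.39 (1.02 to 1.85), and with a minimum of 6 reads the second was 1.11 (1.05 to 1.18) against 1.21 (1.16 to 1.26) for Wdr5.

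**Figure D3:**
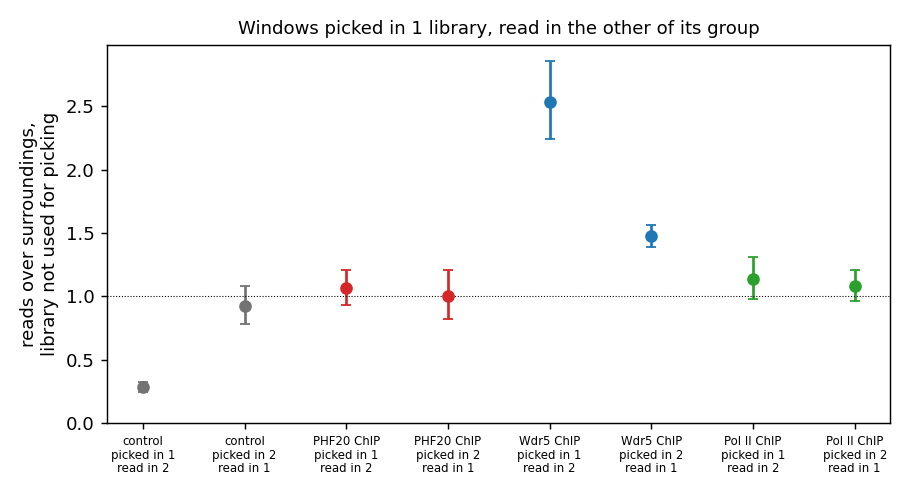
Reads over the surroundings (y axis, ratio) in the library that was not used to pick the 1 kb windows, for each direction in each group (x axis); bars are 95% exact Poisson intervals and the dotted line is a ratio of 1. The 2 Wdr5 points, at 2.53 and 1.47, lie above 1 with their intervals, and those of PHF20 and Pol II include 1.

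PHF20 and Pol II reads where Wdr5 was high were counted at 33 windows of 1 kb. In these, both Wdr5 libraries exceeded both controls at least 3-fold with at least 8 reads each. PHF20 reads there were 1.03 (95% exact Poisson interval 0.79 to 1.32) and 0.84 (0.63 to 1.09) times the surroundings in replicates 1 and 2. Pol II reads were 1.05 (0.80 to 1.34) and 1.27 (0.97 to 1.63) times the surroundings. The windows were picked on the Wdr5 and control libraries. The Wdr5 libraries stood at 5.59 and 5.80, and the controls at 0.68 (0.49 to 0.93) and 0.52 (0.34 to 0.76). The PHF20 intervals rest on 61 and 55 reads and end at 1.32 and 1.09. Ratios near 1 do not bound the presence of PHF20 or Pol II. No windows known to be bound were at hand to show that these libraries detect either target. With a minimum of 6 reads, which gave 109 windows, PHF20 replicate 1 reached 1.28 (1.12 to 1.44) and PHF20 replicate 2 0.95 (0.82 to 1.09). At the same 109 windows both Pol II libraries lay above their surroundings, at 1.203 (1.05 to 1.37) and 1.19 (1.03 to 1.37).

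No 5 kb window was called higher in both PHF20 and Wdr5 ChIP, which was fixed by the 0 calls for Wdr5 in limma-trend and says nothing of shared sites. The log2 fold changes of PHF20 and Wdr5 against control correlated at 0.58 over the 456571 windows, which share their controls and are not independent replicates. Unchanged groups simulated against the same controls gave 0.61 in 20 runs, and the covariance was 0.166 observed and 0.169 simulated. With PHF20 set against control replicate 1 and Wdr5 against control replicate 2 the correlation was -0.02, and with the controls exchanged it was -0.14. Each of these uses 1 control library per arm. Without control replicate 2, the only reference for both comparisons is control replicate 1, which stood apart from the other libraries. Some windows were then called higher in both, which cannot be read as shared sites.

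The third comparison set Pol II ChIP against control. Windows of 5 kb on chromosomes 1, 15, 4 and 13 were higher in Pol II ChIP, 4 in all, and none was lower. They started at 193270001, 87800001, 46275001 and 99810001, with log2 fold changes of 2.71, 2.66, 2.62 and 2.61 and standard errors of 0.51 (limma-trend, adjusted p = 0.0486 each). The Pol II libraries held 10 to 17 reads in these windows and the controls 0 to 5. The PHF20 and Wdr5 libraries also held 4 to 12 reads in these windows. They held 10 or 11 each on chromosome 4, and 6 to 12 on chromosome 15, where each control held 1. Pol II against control was not simulated. In the simulation of PHF20 against control, 17 unchanged windows were called with the profile of control replicate 1, more than the 4 here. When that library was drawn like the others, 2 were called. Pol II was not tested against the other ChIP groups at 5 kb. The number of calls depended on the libraries and settings: 0 without a low-count filter, with a prior count of 0.5, with 20 kb windows, or without either PHF20 or either Pol II library, 43 without control replicate 1 and 178, of which 11 were lower, without control replicate 2. The voom variant of limma called 22 windows, none of them among these 4. In 21 of the 22, control replicate 1 held at most 2 reads. In 14 of the 22, control replicate 2 held as many reads as the lower Pol II library or more. The exact binomial test called 14 higher and 7 lower. At 1 kb no Pol II window passed the threshold in limma-trend. Of the 29867 tested, 1671 had an unadjusted p under 0.05, a share slightly above the 0.05 that chance alone would give. With either control left out, which leaves a single control library, some 1 kb windows were called. Without control replicate 2 most of them were lower in Pol II ChIP.

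A scan of each library against its own surroundings showed that most dense windows were shared between targets. Of 2638999 windows of 1 kb, 383 to 573 per library exceeded the local level at p under 1e-06, where at most 2.64 would do so by chance in Poisson data, and 176 did so in all 8 libraries. The 2 Pol II libraries had 267 such windows in common, of which 2 appeared in no other library. The corresponding numbers were 308 and 4 for PHF20, 289 and 7 for Wdr5, and 228 and 0 for control. The 24 pairs of libraries of different groups shared a median of 3 windows found in no other library, and at most 15, and 6 of the 24 had at least the 7 of the Wdr5 pair. This scan therefore did not set the Wdr5 pair apart. At p under 0.0001 the Wdr5 pair had 36 and the highest of the 24 had 32, and with all reads counted these were 16 and 19. Of the 7 Wdr5 windows, 5 were among the 13 described above.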

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

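The alternatives for the 5 kb comparisons were planned, except the exact binomial test, the crossed blocks and PHF20 against Wdr5, and all alternatives for 1 kb windows were chosen after the data were seen. The chromosome 17 window stayed called in PHF20 against control under all 18 alternatives that gave it a fold change, with log2 values of 3.35 to 5.58 and adjusted p between 3.825e-24 and 0.0013. The 4 Pol II windows stayed called in 7 or 8 of 18 each, with adjusted p of up to 0.861. The cause of these changes was not tested. Depth limits the comparisons to large local changes. Promoter widths, gene lists and shares of reads at promoters were not run.

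PHF20 calls against control numbered 3 with the exact binomial test and 1 to 13 with one library left out. Wdr5 calls went from 0 to 32 with voom, 4 with the exact binomial test and 0 to 176 with one library left out. Pol II calls went from 4, all higher, to 0 with no low-count filter, with a prior count of 0.5 and with 20 kb windows, to 12 with a mean of at least 6 reads, 22 with voom, 21 with the exact binomial test, of which 7 were lower, and 0 to 178 with one library left out. With all reads counted there were 4, of which 1 was lower. PHF20 against Wdr5 went from 1 to 0 with 20 kb windows and to between 1 and 3 with one library left out. With one library left out, PHF20 and Wdr5 calls overlapped only without control replicate 2, where control replicate 1 is the only reference for both. Size factors moved Wdr5 replicate 2 by -0.11 and control replicate 1 by 0.08 on the log2 scale and left the 3 counts against control at 1, 0 and 4.

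The replicate numbers did not pair the libraries in all groups: deviations of replicates 1 and 2 correlated at -0.41 for control with PHF20, -0.33 for PHF20 with Wdr5 and -0.008 for PHF20 with Pol II, but at 0.56 for control with Wdr5, 0.1008 for control with Pol II and 0.1014 for Wdr5 with Pol II. With the number as a block, calls stayed at 1 for PHF20, 0 for Wdr5 and 4 for Pol II. With the control numbers crossed in the block they were 1, 0 and 0, and with the PHF20 numbers crossed, a choice made after those counts had been seen, 1, 1 and 4.

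At 1 kb, with all reads counted, calls against control went from 2 to 6 for PHF20, all higher. They went from 3 to 13 for Wdr5, of which 3 were lower, and from 0 to 2 for Pol II, of which 1 was lower. Wdr5 calls against control were 0 with a mean of at least 6 reads and with a prior count of 0.5. Against the other 6 libraries, they went from 5 to 0 with all reads, with a mean of at least 6 reads and with a prior count of 0.5. With one library left out, the ranges were 2 to 8 for PHF20, 0 to 38 for Wdr5, 0 to 37 for Pol II and 0 to 17 for Wdr5 against the other 6. The 13 windows high in both Wdr5 libraries became 4 at 4-fold and 6 reads, 4 at 4-fold and 8 reads, 2 at 4-fold and 10 reads, and 8 with all reads. With 1 of the other 6 libraries left out there were 13 to 17, a change that can only loosen the rule and so tests nothing.

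The held-out ratios of Wdr5 were 1.85 and 1.21 at 6 reads, 4.82 and 2.16 at 10 reads, and 4.13 and 2.07 at 4-fold, in Wdr5 replicates 2 and 1. Those of Pol II were 1.39 and 1.24 at 10 reads. At windows picked on Wdr5, Pol II replicate 2 stood at 0.652 with 10 reads, 0.762 at 4-fold and 1.19 with 6 reads, where Pol II replicate 1 stood at 1.203. The mean correlation of control replicate 1 with the others turned from 0.101 to -0.0692 with 5 kb windows, where correlations among the other 7 also fell, to between 0.35 and 0.57, and was 0.091 with libraries thinned to the shallowest.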

Other observations

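All tests in this part, and the limits that decide them, were chosen after the patterns and values had been seen. On chromosome 8, replicate 1 of each ChIP held a larger share of distinct starts than replicate 2: 5.65% against 5.19% for PHF20, 5.58% against 5.46% for Wdr5 and 5.69% against 5.28% for Pol II, while the controls held 5.34% and 5.33%. Control replicate 1 alone held 49 windows of 1 kb with at least 12 reads and 4 times the level of every other library, against at most 2 for any other library. The first principal component of the 20 kb windows, with 48.0% of the variance, placed control replicate 1 at 214.7 and Wdr5 replicate 2 at the other end at -147.4.

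The chromosome 17 reads of the PHF20 libraries nearly stopped at 35642931, with 1 start each in the next 400 bp. They were piled at the same 4 starts in both libraries. Binding of PHF20 in the cells as the whole source is argued against by those 4 shared starts and by the end. Past it, 400 bp held only 1.52% as many starts as the 400 bp before the last shared start. The other 6 libraries held 9 starts past it against 4.93 predicted from their flanks. Extra copies of the stretch in cells common to all libraries are argued against by the other 6 libraries, whose upper bound was 1.32 times their flanks. Extra copies only in the cells of the PHF20 libraries stay open, since the labels do not say which libraries shared a culture. A candidate explanation is carried-over DNA of fixed length, such as a PCR product or a cloned fragment, which could give such an end. A single fragment between the first pile and the end would leave out the 43 and 33 starts to the left of it. It would also leave out the 2 starts of PHF20 replicate 2 whose reads ran past the end. The origin of such a fragment was not tested, and PHF20 binding beneath it stays open.

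The Wdr5 pair gave 13 narrow windows and other pairs at most 2 at 3-fold and 8 reads, a favourable setting chosen after all had been seen, but Wdr5 replicate 2 with Pol II replicate 2 gave 17 against 15 at 6 reads and 15 against 8 with all reads counted, so the count leaves chance agreement open. Local density common to all libraries is argued against by the held-out ratios at 8 reads, at most 1.13 for PHF20 and Pol II and at least 1.47 for Wdr5, and the ratio in Wdr5 replicate 2 lay above all of theirs, intervals apart, at each of the 4 settings. The ratio in Wdr5 replicate 1 did not: at 6 reads it was 1.21 (1.16 to 1.26) against 1.11 (1.05 to 1.18) for Pol II, and at 10 reads 2.16 (1.98 to 2.36), with PHF20 at 1.06 (0.344 to 2.47) from 5 windows and Pol II at up to 1.39. As a hypothesis, these windows may be sites of Wdr5 binding, which was found and tested on the same libraries. Base composition and the specificity of the antibody were not tested and stay open.

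The chromosome 8 difference, noticed among 20 chromosomes, followed the replicate number in the 3 ChIP groups and was weighed against 3 explanations. The trend that sets control replicate 1 apart is argued against, because after its removal the difference was 4.54 SD of the other chromosomes for PHF20, 5.84 for Pol II and 2.46 for Wdr5, in which chromosome 4 stood at -2.49. A few high windows are argued against for Pol II, whose medians were higher in replicate 1 in 10 of 10 segments of the chromosome before and after that removal, and stay open for PHF20 and Wdr5, with 18 of 20 after (10 for PHF20 and 8 for Wdr5) and 12 of 20 before (6 each). Extra copies of chromosome 8 in part of the cells of replicate 1 could give ratios of this size, at most 1.08 in medians of 20 kb windows after that removal, but cannot be told apart from an unnamed difference in library preparation, since the labels do not say which libraries shared a culture. Single segments of other chromosomes also differed after that removal. The lowest segment of chromosome 7 stood at log2 differences of -0.2272 for PHF20, -0.1758 for Wdr5 and -0.1985 for Pol II. The highest of chromosome 14 stood at 0.1585, 0.2742 and 0.1478, and that of chromosome 8 at 0.1847, 0.1271 and 0.1451. The design names no biological difference between the replicates.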
